A study of Homo sapiens with 24 samples.

How the data were processed

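RNA sequencing libraries labelled as MCF-7 and ZR-75-1 cells were analysed from 4 deposited tables, each holding 6 libraries. The groups of 3 came from the labels, namely C12orf43 plasmid against control plasmid in ZR-75-1, in the MCF-7 input set and in the MCF-7 second set, and MCF-7 cells given Adriamycin to induce resistance against cells given DMSO. The 4 tables were normalised separately, so every test was made within a table. Bowtie2, RSEM 1.3.1, DESeq2 1.4.5 and the genome build hg38 are named, per the submitters' processing notes. Which of these made which table, and the annotation, are not given in the sources used here. The ZR-75-1 table and the input set hold FPKM for all listed genes, per the labels. The resistance table holds FPKM, per the file headers, for genes whose group means differ by 2-fold or more. The second set holds a normalised expression signal whose unit the deposited table does not name, for genes whose group means differ by 1.5-fold or more. Its column sums, 1.02e6 to 1.37e6 in the controls over the listed genes, rule out TPM, and the test planned for FPKM was used for it. In its overexpression libraries the sums were 2.90e5 to 3.02e5, so the summed signal of the listed genes differed between the groups. The header of that table prefixes the 3 overexpression columns with ZR-75-1, whereas the labels give MCF-7, and the labels were followed.

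Of the listed identifiers, 20958 of 21022, 16572 of 16606, 9269 of 9501 and 2947 of 3040 matched GENCODE release 29 on GRCh38, from which coordinates, exon lengths and GC content were taken. In ZR-75-1, 23 symbols and in the input set 22 had been turned into dates and were not named. No value column was left out, and no pair of libraries was identical.

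Low FPKM values were divided by the worth of 1 read. In the ZR-75-1 experiment and the input set, 96.2 to 97.3% of low values were whole within 0.1 of a read, against 20% from chance, and 94.2% and 94.0% of genes were whole in all 6 libraries. The denominators were 1.89e7, 1.88e7 and 1.68e7 reads in the ZR-75-1 controls and 1.43e7, 2.07e7 and 1.89e7 in the overexpression libraries. In the input set they were 1.54e7, 1.96e7 and 1.30e7 reads and 1.78e7, 2.40e7 and 2.29e7. The genes whole in all 6 libraries held 84.7 to 89.4% of those reads in the ZR-75-1 controls and 94.6 to 95.6% in the overexpression libraries. In the resistance table, 51.2 to 57.9% of low values were whole and in the second set 19.6 to 21.7%, so their depth is unknown. Recovered reads cover counting error only.

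The main test was limma 3.58.1 in R 4.3.3, with a mean-variance trend, on log2(value + 1) for genes at 1 or more in at least 3 of the 6 libraries. Genes with a Benjamini-Hochberg adjusted p under 0.05 counted as changed. Fold changes are on the log2(value + 1) scale, which understates changes of low genes. C12orf43 was also tested with a 2-sided exact permutation test. A set of 27 gene lists was fixed before the data were examined, as were the tests and the other settings to try. They were study genes, p53 targets, polycomb complexes, HOX genes, S phase and DNA replication, G2/M and mitosis, oestrogen response, drug efflux and metabolism, luminal epithelium, mesenchymal and EMT, basal and myoepithelial, fibroblast, immune cell, ovarian and Mullerian epithelium and interferon-stimulated genes. The others were NF-kB and inflammatory genes, the unfolded protein and integrated stress response, heat shock, NRF2 and oxidative stress, hypoxia and glycolysis, cholesterol synthesis, canonical Wnt targets, ribosome biogenesis, ribosomal proteins, apoptosis regulators, homologous recombination and DNA damage, and mitochondrially encoded genes. In ZR-75-1 and the input set, lists with 5 or more tested members were compared with all other genes by camera, with a preset correlation of 0.01 and Benjamini-Hochberg over lists, and again with an estimated correlation. In the selected tables only members were counted. Members that passed were counted over all genes and adjusted over the list alone. Genes changed in 2 experiments were counted per direction among those tested in both, with a 1-sided Fisher's exact test for excess, or for fewer than expected, the latter printed after seeing the opposite fold changes.

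Genes were named by a rule fixed beforehand. It took the study genes C12orf43, NAT10, BMI1, TP53, CDKN1A, MDM2 and ABCB1 wherever listed, and the 8 largest rises and 8 largest falls among changed genes with no overlap between groups and a mean of 2 or more in 1 group. It also took up to 4 members per list with the smallest p, or 2 where none passed. AC132872.3, ESR1, PGR, GATA3, FOXA1, CDH1, EPCAM, VIM, MTAP, CDKN2A and, as markers, KRT8, KRT18 and KRT19 were chosen after their values were seen.

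On simulated data with the real means and spread, 42%, 84%, 100% and 100% of genes changed by 0.5, 1, 2 and 3 on the log2 scale were recovered in the ZR-75-1 setting of 13719 genes. In the input set setting of 11704 genes these were 0%, 4%, 42% and 72%, in the second-set setting of 8503 genes 30%, 94%, 100% and 100%, and in the resistance setting of 1871 genes 80%, 98%, 100% and 100%. A list shifted on purpose was called by camera and 0 of 20 unshifted lists were. Genes varied independently in that simulation, so it does not cover lists whose members move together. In ZR-75-1 the estimated correlation of the ribosomal proteins was 0.98.

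Settings chosen beforehand were pseudocounts of 0.1 and 0.01, no filter and a filter at 5, median-of-ratios scaling, quantile normalization, no mean-variance trend, a log2 fold change of 1 or more, the replicate number as a block, and each library left out. Those chosen after seeing the data were removing a trend in exon length, in GC content or in both from each library, limma voom on recovered reads (ZR-75-1 and the input set), lists with each library left out or with quantile normalization, and overlaps under the scalings and trends or without C12orf43. Tables were read and figures drawn with Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.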

Results

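RNA levels were measured in 24 libraries labelled as human breast cancer lines, in 4 comparisons of 3 libraries against 3. MCF-7 and ZR-75-1 are established breast cancer lines that are known as luminal and oestrogen receptor-positive. In 3 comparisons, cells with a C12orf43 plasmid were set against cells with a control plasmid. They were 1 experiment in ZR-75-1, a set of MCF-7 libraries whose labels carry the word input (the MCF-7 input set) and another set of MCF-7 libraries (the MCF-7 second set). The fourth comparison set MCF-7 cells given Adriamycin to induce resistance (resistant cells) against MCF-7 cells given the solvent DMSO (sensitive cells), so it includes exposure to the drug. Adriamycin is doxorubicin, an anthracycline that traps topoisomerase II on DNA. The series title links C12orf43 to NAT10, the enzyme that writes N4-acetylcytidine on RNA, to the polycomb protein BMI1, to p53 and to resistance.

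The ZR-75-1 table listed 21022 genes and the MCF-7 input set 16606. The second set listed 9501 genes, none with group means within 1.5-fold of each other, and the resistance table held 3040, none within 2-fold, so both are selections of changed genes. In the FPKM of the ZR-75-1 experiment and of the input set, low values were steps of whole reads, which put depth at 1.43e7 to 2.07e7 and 1.30e7 to 2.40e7 reads per library. The depth of the second set and the resistance libraries is unknown. Values below are means ± SD of n = 3 libraries in each table's own unit. The labels do not say that libraries came from separate cultures, so p-values measure only the spread between these libraries, which may be technical.

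Several markers expected in luminal lines were low or not listed, while the keratins KRT8 and KRT18 were high. ESR1, the oestrogen receptor, lay between 0.0279 and 0.0767 FPKM in the 6 ZR-75-1 libraries, on 6 to 20 reads each, and was not listed in the other tables, nor was the progesterone receptor PGR in any table. In the ZR-75-1 controls the adhesion gene CDH1 was at 0.388 FPKM, while VIM, a mesenchymal intermediate filament, was at 149 FPKM. Other luminal or epithelial genes there were GATA3 at 0.264 FPKM, the keratin KRT19 at 0.412, EPCAM at 1.63 and FOXA1 at 2.34. VIM was at 154 FPKM in the input set controls, with CDH1 at 1.27, FOXA1 at 2.01, EPCAM at 2.23 and KRT19 at 9.50, and GATA3 was not listed. In sensitive cells of the resistance comparison VIM was at 133 FPKM and CDH1 at 0.229. The luminal keratins KRT8 and KRT18 were at 262 and 240 FPKM in the ZR-75-1 controls and at 545 and 697 FPKM in the input set controls. MTAP, which MCF-7 cells are known to lack through a deletion, lay between 2.0 and 4.11 FPKM in the 6 input set libraries. CDKN2A, known to be lost in the same deletion, lay between 35.0 and 64.1 FPKM there and between 137 and 1390 in normalised expression in the second set.

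C12orf43 (ENSG00000157895, chromosome 12, 121000486 to 121016502 on the minus strand, protein-coding, GRCh38), also called CUSTOS, rose in all 4 comparisons. It went from 3.03 ± 0.0611 to 50.7 ± 1.26 FPKM in ZR-75-1, on 311 to 357 reads in the controls, and from 6.29 ± 1.89 to 128 ± 14.9 FPKM in the input set. In the second set, normalised expression went from 5.37 ± 2.03 to 1635 ± 93.1. Resistant cells, for which the labels name no plasmid, had 813 ± 31.8 FPKM against 4.63 ± 0.326 in sensitive cells. The log2 fold changes were 3.68 (SE 0.0631), 4.18 (SE 0.266), 8.06 (SE 0.196) and 7.18 (SE 0.0644). The limma adjusted p-values were 2.2e-06, 0.000231, 8.43e-12 and 1.82e-11. The 2-sided exact permutation test gave p = 0.1 each time, the smallest that 3 against 3 allows. The 4 tables were normalised separately, and levels were not tested across them.

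**Figure D1:**
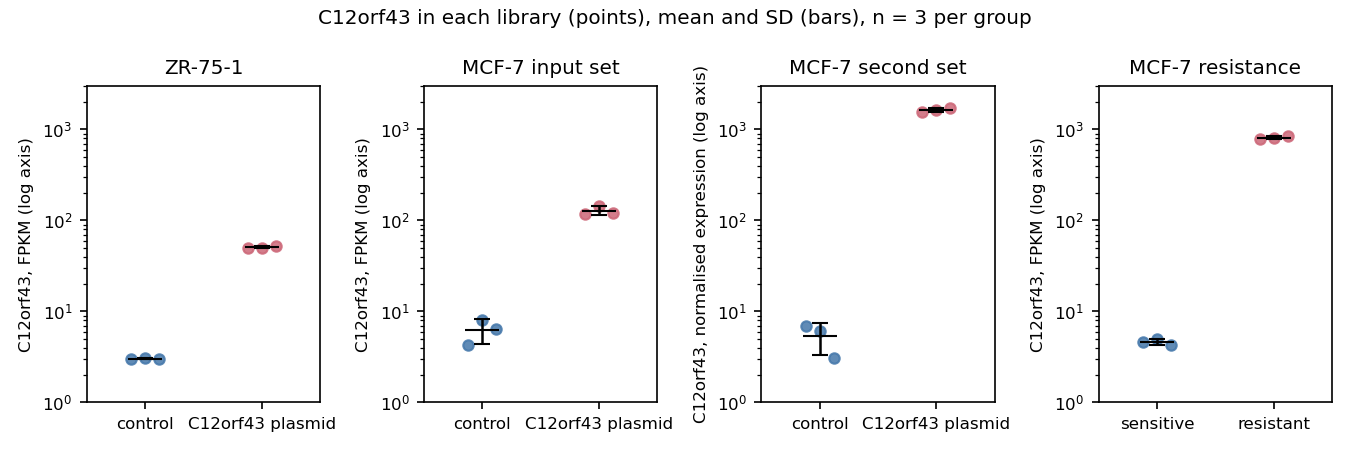
C12orf43 in each library on a log axis, in FPKM or, for the MCF-7 second set, normalised expression; points are libraries and bars the mean and SD of 3. In every panel the lowest library of the C12orf43 plasmid or resistant group lay above the highest control, by 14.7 to 225 times.

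In ZR-75-1 cells with the C12orf43 plasmid, the transcription factor genes JUN, EGR1 and FOSB were among the largest falls. JUN went from 87.3 ± 19.2 to 16.9 ± 3.04 FPKM, EGR1 from 152 ± 25.7 to 33.2 ± 2.71 and FOSB from 8.72 ± 0.615 to 1.23 ± 0.164. LPL, lipoprotein lipase, fell from 13.0 ± 0.345 to 0.703 ± 0.165 FPKM (log2 fold change -3.04, limma adjusted p = 5.47e-05). Among the largest rises were CITED4, a transcriptional co-regulator, from 9.29 ± 4.99 to 66.6 ± 10.7 FPKM, the metallothionein MT1E from 10 ± 4.24 to 59.9 ± 1.64, and the mitochondrial protein gene CHCHD10 from 6.3 ± 3.65 to 40.2 ± 3.96. For these rises control 3, at 15.1, 14.9 and 10.5 FPKM, lay between the other controls and the overexpression libraries. A part of the difference was thus also present among the controls. For JUN, EGR1 and FOSB, control 3 was instead the control farthest from the overexpression libraries. Of 13829 genes tested, 7283 changed, 4123 up and 3160 down, with limma and Benjamini-Hochberg adjustment. Up calls were 56.6% of the total, and 44.1% with voom on the recovered reads.

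Of the genes in the series title, NAT10 (chromosome 11, 34105602 to 34147670) rose in ZR-75-1 from 18.8 ± 0.556 to 23.4 ± 1.37 FPKM (log2 fold change 0.30, limma adjusted p = 0.0134). BMI1 (chromosome 10, 22321211 to 22331484) rose from 3.42 ± 0.178 to 4.38 ± 0.241 FPKM (log2 fold change 0.28, limma adjusted p = 0.0195). The NAT10 call was lost with quantile normalization (0.09) and without control 1 (0.28), overexpression 2 (0.29) or overexpression 3 (0.26). The BMI1 call was lost without control 2 (0.29), overexpression 1 (0.25) or overexpression 2 (0.29). TP53 was at 11.6 ± 0.926 against 12.7 ± 0.628 FPKM (limma adjusted p = 0.237) and passed without control 3, at a log2 fold change of 0.18. The p53 targets CDKN1A, which encodes p21, and MDM2, which encodes the ligase that degrades p53, did not pass. CDKN1A was at 37.5 ± 8.64 against 29.1 ± 2.5 FPKM (limma adjusted p = 0.119). It passed as lower with quantile normalization (log2 fold change -0.60), with the length trend, the GC trend or both removed, and with voom on the recovered reads. MDM2 was at 5.95 ± 1.09 against 4.8 ± 0.257 FPKM (limma adjusted p = 0.135) and passed without control 3 (-0.39).

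Other genes picked by size in ZR-75-1 were small RNAs and a short protein-coding gene. Mitochondrial tRNA genes rose, MT-TA from 2.63 ± 1.1 to 23.8 ± 8.45 FPKM, MT-TI from 2.21 ± 1.87 to 14.3 ± 1.02 and MT-TC from 15.5 ± 24.1 to 273 ± 311. The MT-TC call was lost without control 1 (log2 fold change 4.04), control 2 (4.04) or overexpression 1 (3.81). Genes this short have few reads behind low FPKM values, so these rises are uncertain. C4orf48 rose from 2.67 ± 2.04 to 16.8 ± 3.19 FPKM. RN7SL2, an RNA of the signal recognition particle with near-identical copies, fell from 481 ± 237 to 79.9 ± 16.7 FPKM, which is uncertain. MIR616 fell from 5.29 ± 1.15 to 0.166 ± 0.288 FPKM and MIR3153 from 25.5 ± 5.69 to 4.26 ± 1.04, also uncertain, since reads of overlapping transcripts can count for either. SNORD117, also short, fell and was listed at 0 in the 3 overexpression libraries, which is uncertain for the same reason as the tRNA genes.

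Most tested members rose in ZR-75-1 in the 5 lists given here, and also in the luminal and HOX lists given below. Of 42 ribosomal protein genes tested, 37 rose and 0 fell (38 and 0 adjusted over the list alone), with a median log2 fold change of 0.96. RPLP2 went from 36.5 ± 19.5 to 129 ± 5.26 FPKM and RPS15 from 63.6 ± 27.2 to 182 ± 9.31. Of 39 ribosome biogenesis genes, 27 rose and 0 fell (29 and 0 adjusted over the list alone), among them PNO1, from 6.94 ± 0.396 to 16.7 ± 0.595 FPKM, and NOP56, from 16.1 ± 0.733 to 31.8 ± 2.29. Of 14 heat shock genes, 13 rose and 0 fell over all genes and adjusted over the list alone, such as HSPA8, from 112 ± 6.27 to 275 ± 20.6 FPKM, and DNAJA1, from 54.6 ± 3.02 to 101 ± 6.74. Of 21 NRF2 and oxidative stress genes, 16 rose and 1 fell by either adjustment, such as NQO1, from 48.3 ± 7.88 to 102 ± 5.28 FPKM, and FTL, from 830 ± 311 to 2328 ± 10.7. Of 13 mitochondrially encoded genes, 11 rose and 0 fell by either adjustment, with MT-ND1 from 2880 ± 821 to 6235 ± 281 FPKM. Control 3 stood apart from the other two controls, with ribosomal proteins at 4.19% of summed FPKM against 2.98% and 2.95%, and 4.54 to 4.73% in the overexpression libraries, and with RPLP2 at 59.0 against 25.5 and 25.1 FPKM. Without control 3, 42 of 42 ribosomal proteins rose, with a median of 1.21, and with quantile normalization 24 rose and 3 fell, with a median of 0.52. Under that normalization 17 ribosome biogenesis, 9 heat shock, 10 NRF2 and oxidative stress and 7 mitochondrially encoded genes rose. In camera, which compares a list with all other genes, adjusted p was 2.09e-07, 2.4e-07, 2.2e-05, 0.00123 and 0.000302 for these lists in turn. No list of this experiment passed with an estimated correlation, where adjusted p = 0.622 to 0.691 for these 5.

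In 4 further lists of ZR-75-1 that were lower in camera, some members fell, some did not pass and, in all but the first, some rose. Of 30 hypoxia and glycolysis genes in ZR-75-1, 0 rose and 15 fell (median -0.54), by either adjustment. The glucose transporter SLC2A3 went from 89.2 ± 4.0 to 21.5 ± 2.91 FPKM and the hexokinase HK2 from 47.6 ± 2.54 to 16.7 ± 1.4. Of 28 cholesterol synthesis genes, 2 rose and 13 fell (median -0.07), among them INSIG1, from 47.4 ± 0.816 to 13.9 ± 1.47 FPKM, and the lipid desaturase SCD, from 342 ± 20.1 to 102 ± 7.04. Of 31 mesenchymal genes, 7 rose and 16 fell (median -0.31), such as FN1, from 78.3 ± 4.29 to 22.6 ± 1.01 FPKM, and LOX, from 28.0 ± 1.6 to 10.2 ± 1.39. Of 29 homologous recombination and DNA damage genes, 3 rose and 12 fell, with EXO1 from 34.0 ± 2.06 to 23.3 ± 0.534 FPKM, while the histone variant H2AFX rose from 19.9 ± 7.69 to 61.7 ± 2.85. Of 15 luminal genes, which were higher in camera, 9 rose and 0 fell, with the keratin KRT18 from 240 ± 57.1 to 438 ± 29.6 FPKM and the splicing factor ESRP2 from 3.04 ± 0.274 to 6.14 ± 0.415. These counts were the same adjusted over the list alone. In camera, adjusted p was 3.54e-06, 0.0316, 0.0118, 0.00416 and 0.00813 in turn, and with an estimated correlation adjusted p = 0.622, 0.622, 0.622, 0.628 and 0.657.

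Fold changes in ZR-75-1 followed the GC content of a gene's exons, with a Spearman rho of 0.39 across genes, which are not independent replicates, and -0.26 with exon length. With the GC trend removed, the luminal call was lost (camera adjusted p = 0.156), and with the length trend removed the luminal and mesenchymal calls were lost (0.0519 each). With both removed, the calls of luminal epithelium (0.26) and homologous recombination and DNA damage (0.0775) were lost. The cholesterol call was lost without control 3 (camera adjusted p = 0.289). Calls were gained as well. S phase and DNA replication passed as lower with the length trend (0.00117), the GC trend (0.0245) or both (0.000644) removed and with quantile normalization (0.000395). The unfolded protein and integrated stress response passed as lower with the length trend (0.0330) or both (0.0422) removed and with quantile normalization (0.0155). G2/M and mitosis passed as higher with the GC trend removed (0.0275), and HOX genes with quantile normalization (0.0155) and without control 1 (0.0480).

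The other lists did not pass camera in ZR-75-1 on the values as deposited. Of 31 p53 targets, 10 rose and 8 fell by either adjustment (camera adjusted p = 0.944), with BAX, which promotes apoptosis, up from 6.12 ± 1.5 to 15.7 ± 0.272 FPKM and the repair gene XPC down from 17.6 ± 0.517 to 11.5 ± 0.0341. Of 35 S phase genes, 3 rose and 12 fell (3 and 10 adjusted over the list alone, camera adjusted p = 0.103), with CCNE2 down from 15.6 ± 2.22 to 7.65 ± 0.0935 FPKM. Of 35 G2/M and mitosis genes, 12 rose and 6 fell by either adjustment (0.492), with the mitotic kinase PLK1 up from 17.6 ± 2.22 to 41.8 ± 1.18 FPKM. Of 18 HOX genes, 10 rose and 2 fell (11 and 2 adjusted over the list alone, 0.0693). Of 28 unfolded protein and integrated stress response genes, 7 rose and 10 fell by either adjustment (0.158). Of 25 interferon-stimulated genes, 6 rose and 5 fell (5 and 5 adjusted over the list alone, 0.919), and of 14 NF-kB and inflammatory genes 6 rose and 4 fell by either adjustment (0.851). The same by either adjustment, 4 rose and 2 fell of 12 Wnt targets (0.646), 3 and 4 of 10 basal genes (0.811), 3 and 3 of 6 fibroblast genes (0.944) and 3 and 0 of 6 study genes (0.330). Of 7 ovarian and Mullerian epithelium genes 2 rose and 1 fell (3 and 1 adjusted over the list alone, 0.851), and the 1 immune gene tested fell.

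In the MCF-7 input set, NAT10 rose as C12orf43 did, from 18.7 ± 2.12 to 204 ± 3.02 FPKM (log2 fold change 3.39, SE 0.184, limma adjusted p = 0.00011). NCOA5, a nuclear receptor coactivator, rose from 3.19 ± 0.6 to 31.6 ± 9.76 FPKM. S100A14, a calcium-binding protein gene, fell from 11.3 ± 1.15 to 0.186 ± 0.177 FPKM and WDYHV1, an N-terminal glutamine amidohydrolase gene, from 10.2 ± 1.43 to 0.183 ± 0.0931. The stress genes GADD45B and DDIT4 fell from 64.2 ± 2.82 to 16.8 ± 1.32 FPKM and from 526 ± 49.1 to 232 ± 25.4. Reads of BMI1 numbered 0, 2 and 2 in the controls and 132, 173 and 47 with the C12orf43 plasmid, under the level needed for the test. Values near 0 beside clear signal also occurred within a group. In the controls EPCAM lay between 0 and 5.46 FPKM and KRT19 between 0.139 and 15.9. From 1565 to 3614 listed genes were at 0 per library. The BMI1 difference is thus uncertain.

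Of 11138 genes tested in the input set, 8 changed, 4 up and 4 down, with limma and Benjamini-Hochberg adjustment, and 1097 had an unadjusted p under 0.05. The eighth was the antisense gene AC132872.3, up to 17.4 ± 5.59 FPKM, which is uncertain because the counting is not stated to use strand. C12orf43 and NAT10 passed without any 1 of the 6 libraries. The other named genes were lost in each such fit, with limma adjusted p from 0.0616 to 0.199 for NCOA5 and from 0.0986 to 0.20 for S100A14. Their ranges were 0.103 to 0.226 for WDYHV1, 0.0651 to 0.153 for GADD45B and 0.0675 to 0.190 for DDIT4. Replicates correlated at 0.810 to 0.899, against 0.807 to 0.878 between groups. In data simulated with this spread, 4% of genes changed by 1 on the log2 scale were recovered and 72% of those changed by 3.

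TP53 in the input set was at 14.1 ± 1.12 FPKM in the controls and 9.33 ± 0.263 with the plasmid (limma adjusted p = 0.599). CDKN1A was at 26.4 ± 14.7 against 26.7 ± 15.2 FPKM (0.995) and MDM2 at 3.76 ± 0.794 against 5.05 ± 1.02 (0.837). ABCB1, the drug efflux pump P-glycoprotein, was listed at 0 in 5 libraries and at 0.270 FPKM in overexpression 3.

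**Figure D2:**
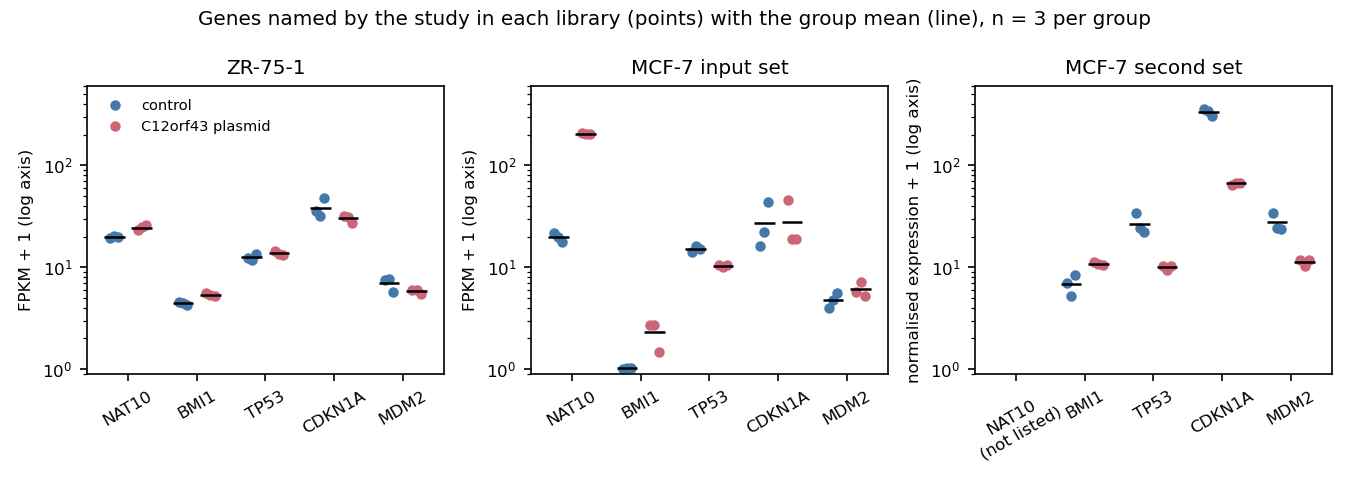
Genes named by the study in each library of the 3 overexpression experiments, as value plus 1 on a log axis; points are libraries and lines the mean of 3, in FPKM or, for the second set, normalised expression. NAT10 stood at 204 FPKM against 18.7 in the input set and at 23.4 against 18.8 in ZR-75-1. It was not listed in the second set, which holds only genes whose group means differ by 1.5-fold or more.

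In the input set 8 lists passed camera, although few or none of their members passed alone. Of 27 cholesterol synthesis genes tested, 0 rose and 0 fell over all genes, and 6 rose and 0 fell adjusted over the list alone, with a median log2 fold change of 0.73 and camera adjusted p = 4.38e-07. MVK was at 1.93 ± 2.82 against 10.5 ± 4.88 FPKM and SCD at 98.8 ± 7.16 against 177 ± 36.8. Of 39 ribosome biogenesis genes, 1 rose, which was NAT10 itself, and 0 fell (2 and 0 adjusted over the list alone), with a median of 0.62 and camera adjusted p = 7.61e-07. Heat shock (0 of 14 rose, 1 adjusted over the list alone, camera adjusted p = 0.0265) and the study genes (2 of 5 rose by either adjustment, C12orf43 from the plasmid and NAT10, 0.0103) were also higher in camera. Mesenchymal genes (0 of 32 changed by either adjustment, median -0.28) and basal genes (0 of 15 changed, 1 fell adjusted over the list alone, median -0.40) were lower, with camera adjusted p = 0.0103 and 0.0194. Keratin KRT5, a basal gene, was at 32.8 ± 4.44 against 8.61 ± 2.57 FPKM. Ribosomal proteins (0 of 42 by either adjustment, median -0.16) and mitochondrially encoded genes (0 of 13, 1 rose and 5 fell adjusted over the list alone, median -0.28) were lower, with camera adjusted p = 0.0352 and 0.0361. None of the 8 lists passed with an estimated correlation, where adjusted p = 0.162 for cholesterol synthesis, 0.236 for the study, mesenchymal and basal genes, 0.424 for ribosome biogenesis and 0.474 for the other three. The mitochondrial call was lost with quantile normalization (0.218) and without control 1 (0.0952), control 3 (0.122), overexpression 1 (0.0537) or overexpression 3 (0.175).

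Camera calls of heat shock, basal genes and ribosomal proteins in the input set were also lost without single libraries. Heat shock was lost without control 3 (0.215), overexpression 2 (0.112) or overexpression 3 (0.0788), and basal genes without control 2 (0.194). Ribosomal proteins were lost without control 1 (0.0902), control 2 (0.117), control 3 (0.0713), overexpression 1 (0.224) or overexpression 3 (0.0849). In the lists that did not pass, 0 genes changed over all genes except DDIT4 of the unfolded protein and integrated stress response (0 rose and 1 fell of 28, 3 and 6 adjusted over the list alone, camera adjusted p = 0.364). Adjusted over the list alone, 2 of 14 NF-kB genes (0.153) and 2 of 30 hypoxia genes (0.153) fell. By either adjustment 0 changed of 30 p53 targets (0.153), 34 S phase genes (0.697), 35 G2/M genes (0.864), 17 HOX genes (0.864), 15 luminal genes (0.813), 21 NRF2 genes (0.813), 18 interferon-stimulated genes (0.703) and 12 Wnt targets (0.727). The same held for 29 homologous recombination genes (0.813), 5 fibroblast genes (0.252), 5 ovarian genes (0.581) and the 1 immune gene tested. Without control 1, NF-kB and inflammatory genes passed camera as lower (0.0295), and without overexpression 1, hypoxia and glycolysis genes did (0.00130). GDF15, a p53 target, was at 23.1 ± 12.2 against 4.18 ± 2.73 FPKM.

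In the MCF-7 second set, interferon-induced IFIT genes rose from near the floor with the C12orf43 plasmid. IFIT2 went from 0.739 ± 0.234 to 22.0 ± 1.12, IFIT3 from 0.623 ± 0.0738 to 13.4 ± 1.46, IFIT1 from 1.35 ± 0.401 to 15.9 ± 1.32 and the ISG15 ligase HERC5 from 2.48 ± 0.271 to 21.5 ± 3.2, in normalised expression. BMI1 rose from 5.84 ± 1.55 to 9.78 ± 0.371 (log2 fold change 0.68, limma adjusted p = 0.00143), a call lost with the GC trend removed (0.07). TP53 fell from 25.7 ± 6.35 to 8.97 ± 0.53 (-1.40, limma adjusted p = 1.33e-06), CDKN1A from 334 ± 27.9 to 65.4 ± 1.61 (-2.33, 1.72e-10) and MDM2 from 26.5 ± 5.86 to 10.3 ± 0.792 (-1.26, 2.57e-06). These falls stand beside a median log2 fold change of -0.93 over all tested genes of this set. Summed values of the listed genes were 1.02e6 to 1.37e6 in the controls and 2.90e5 to 3.02e5 with the plasmid. NAT10 and ABCB1 were not listed in this table, which holds only genes whose group means differ by 1.5-fold or more. The rise of NAT10 in the input set thus had no listed counterpart here. Its header prefixes the 3 overexpression columns with ZR-75-1, while the labels give MCF-7.

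Among the largest rises in the second set were also CCNL1, a cyclin that acts in splicing, from 5.74 ± 1.29 to 37.4 ± 1.75, the nuclear matrix gene MATR3 from 2.53 ± 0.759 to 18.1 ± 2.41, and HMGCS1, an enzyme of cholesterol synthesis, from 13.7 ± 4.35 to 73.1 ± 4.65. Among the largest falls were TRAPPC5 from 1153 ± 131 to 46.3 ± 5.64, CCDC85B from 1870 ± 423 to 80.6 ± 13.7 and BOP1, a ribosome biogenesis factor, from 436 ± 71.2 to 21.4 ± 0.719. NAA38 (-4.44), NDUFS7 (-4.30), MCRIP2 (-4.23), ZNF593 (-4.22) and TPGS1 (-4.22) fell by similar log2 steps. Of 8687 genes tested in this selected table, 8678 passed limma with Benjamini-Hochberg adjustment, 3456 up and 5222 down. The median log2 fold change of all tested genes was -0.93, and -0.05 with median-of-ratios scaling or -0.00 with quantile normalization. Up calls were 39.8% of the total, and 49.1% and 50.6% under those scalings. They were 52.0% with the length trend removed and 56.8% with the GC trend removed.

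**Figure D3:**
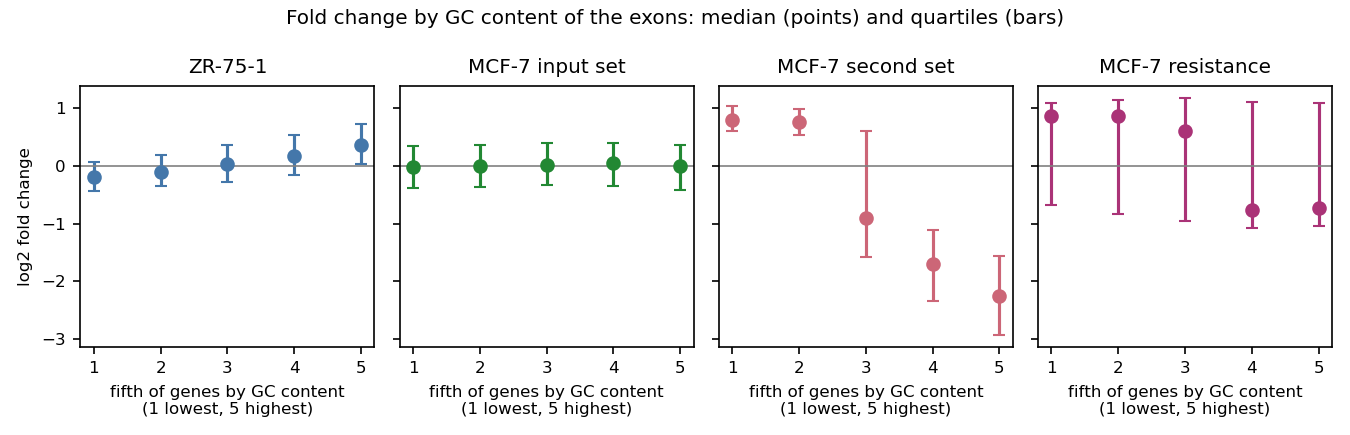
Log2 fold change by quintile of genes ordered by the GC content of their exons, in each comparison; points are medians and bars the lower and upper quartiles. In the MCF-7 second set the median went from 0.79 in the quintile with the lowest GC content to -2.24 in the highest, and in ZR-75-1 from -0.20 to 0.37.

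Fold changes of the second set followed GC content with a Spearman rho of -0.74 across genes, and exon length with 0.43. Members of its lists are selected genes, so no list was tested against the others, and medians below are read against the shift of all genes. That shift differed with GC content, from 0.79 in the lowest quintile to -2.24 in the highest. The rho stayed at -0.75 with median-of-ratios scaling and -0.73 with quantile normalization, so the median of a list may follow the GC content of its members. The counts were the same adjusted over the list alone. Of 26 G2/M genes, 20 rose and 6 fell (median 1.36, and 2.31 and 2.34 under the other scalings), with the kinesin KIF20A up from 10.1 ± 1.32 to 35.1 ± 2.34 and CCNB2 from 34.1 ± 1.23 to 99.3 ± 5.01. PLK1 of the same list fell from 205 ± 20.5 to 70.5 ± 2.01 (-1.53), but was higher with quantile normalization (0.57), and its sign also turned with the GC trend removed. Of 25 interferon-stimulated genes, 13 rose and 12 fell (median 0.75, mean -0.05), with IFITM3 down from 1460 ± 126 to 184 ± 6.79 and ISG15 down from 3763 ± 747 to 387 ± 3.24. Of 19 homologous recombination genes, 15 rose and 4 fell (median 0.71), with BRCA1 up from 0.576 ± 0.177 to 2.73 ± 0.418 and XRCC3 down from 185 ± 9.54 to 17.1 ± 0.394. Of 6 mitochondrially encoded genes, 5 rose and 1 fell (median 0.79), with MT-ND5 up from 308 ± 32.3 to 977 ± 157. MT-ND3 fell from 7579 ± 2115 to 2094 ± 92.3 (-1.82), but was higher with quantile normalization (0.40).

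Epithelial keratins and ribosomal protein genes were among those lower in the second set. Of 10 luminal genes, 1 rose and 9 fell (median -2.08, and -1.22 and -0.97 under the other scalings), with KRT8 from 3369 ± 403 to 369 ± 4.78 and KRT18 from 2315 ± 418 to 343 ± 8.82. Of 33 ribosomal protein genes, 2 rose and 31 fell (median -1.65), but the median was 0.40 with quantile normalization. RPL35 went from 33184 ± 1834 to 2462 ± 71.3 and RPL28 from 7890 ± 948 to 738 ± 17. The medians of HOX, NF-kB and hypoxia genes lay near the shift of all tested genes (-0.93). Of 11 HOX genes, 0 rose and 11 fell (median -0.89, and -0.04 and -0.63 with median-of-ratios scaling and quantile normalization), with HOXB4 from 94.5 ± 13.4 to 27.8 ± 2.67, a call lost with quantile normalization (-0.08). Of 13 NF-kB genes, 3 rose and 10 fell (median -1.18, and -0.43 and -0.85). Of 19 hypoxia and glycolysis genes, 5 rose and 14 fell (median -1.04, and -0.10 and -0.06), with TPI1 from 4707 ± 462 to 537 ± 18.6. Of 17 NRF2 genes, 5 rose and 12 fell (median -1.47), but 0.57 with quantile normalization, with the pentose phosphate enzyme TKT down from 1378 ± 116 to 159 ± 7.11. Basal genes (2 rose and 5 fell of 7, median -1.25) were lower under each scaling, and Wnt targets (1 and 6 of 7) had a median of -0.77, or 0.09 with median-of-ratios scaling.

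Lists of the second set whose median changed sign with the scaling stood as follows. Of 21 p53 targets, 10 rose and 11 fell (median -0.69, and 0.28 and 0.39 with median-of-ratios scaling and quantile normalization), with FDXR down from 74.9 ± 8.1 to 7.02 ± 0.33 and PLK3 from 39.9 ± 2.76 to 6.9 ± 0.742. Of 21 S phase genes, 9 rose and 12 fell (-0.65, 0.36 and 0.59), with CDT1 down from 513 ± 51.5 to 52.5 ± 5.13 and E2F1 from 47.5 ± 7.09 to 5.08 ± 0.71. Of 22 ribosome biogenesis genes, 9 rose and 13 fell (-0.85, 0.12 and 0.13), and of 22 cholesterol synthesis genes 10 rose and 12 fell (-0.78, 0.23 and 1.03). Of 22 mesenchymal genes, 9 rose and 13 fell (-0.76, 0.27 and 0.61). Of 20 unfolded protein and integrated stress response genes, 9 rose and 11 fell (-1.09, -0.17 and 0.48). Of 6 heat shock genes, 3 rose and 3 fell (median 0.01, mean -0.31). Of the study genes 2 rose and 3 fell, of 3 ovarian genes 1 rose and 2 fell, and the 1 fibroblast and 2 immune genes fell.

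Adriamycin-resistant MCF-7 cells had higher stress and inflammatory transcripts than sensitive cells. GADD45A, a DNA damage response gene, rose from 6.58 ± 0.36 to 167 ± 2.73 FPKM and DDIT3, the stress transcription factor CHOP, from 6.92 ± 0.295 to 123 ± 8.26. The phosphatase gene DUSP5 rose from 5.26 ± 0.123 to 107 ± 3.06 FPKM, PHLDA1 from 3.05 ± 0.208 to 65.3 ± 1.14 and TMEM265 from 0.112 ± 0.019 to 30.2 ± 6.42. FAM136A (chromosome 2, 70295975 to 70302090), which encodes a mitochondrial protein, rose from 23.9 ± 0.566 to 12619 ± 744 FPKM (log2 fold change 8.98, limma adjusted p = 4.78e-12). Its pseudogene copy FAM136CP rose from 0.0413 ± 0.0716 to 15.5 ± 3.51 FPKM, which is uncertain.

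TP53 (chromosome 17, 7661779 to 7687550) fell in resistant cells, from 15.5 ± 0.958 to 3.77 ± 0.0254 FPKM (log2 fold change -1.79, limma adjusted p = 3.45e-08). NAT10, BMI1, CDKN1A, MDM2 and ABCB1 were not listed in this table. SLC12A3, a sodium chloride transporter gene, fell from 10.9 ± 0.514 to 0.153 ± 0.0132 FPKM, CPS1 of the urea cycle from 97.4 ± 3.49 to 11.7 ± 1.38, PEG10 from 30.0 ± 1.28 to 4.82 ± 0.529 and MYLK3 from 4.73 ± 0.314 to 0.21 ± 0.0212. Mitochondrial transcripts fell as well, with MT-ATP8 from 6584 ± 355 to 895 ± 97.5 FPKM, MT-ND3 from 3426 ± 277 to 693 ± 54.2 and MT-ATP6 from 5056 ± 233 to 1075 ± 46.6. MTATP6P1, a nuclear copy of MT-ATP6, fell from 858 ± 42.6 to 182 ± 10.3 FPKM, which is uncertain. Of 2095 genes tested in this selected table, 2094 passed limma with Benjamini-Hochberg adjustment, 1083 up and 1011 down.

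The median log2 fold change of the tested genes in the resistance table was 0.62, and 1.09 with median-of-ratios scaling or -0.13 with quantile normalization. Up calls were 51.7% of the total and 61.7% with median-of-ratios scaling. Fold changes followed exon length with a Spearman rho of -0.43 across genes and GC content with -0.18.

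Every tested member of some lists was higher in resistant cells. Among them were 17 of 17 NF-kB and inflammatory genes (median 1.95), from a list of 29, as selected for the table. So were 13 of 13 unfolded protein and integrated stress response genes (median 1.83), from a list of 30. The same held for 4 of 4 heat shock genes, from a list of 14, and 5 of 5 ribosomal protein genes, from a list of 42. Members not listed did not meet the selection. The chemokine CXCL8 rose from 0.456 ± 0.0943 to 17.5 ± 1.82 FPKM, IL6 from 0.421 ± 0.029 to 6.43 ± 0.325 and LIF from 4.0 ± 0.18 to 20 ± 0.792, and CSF2, listed at 0 in sensitive cells, was at 11.4 ± 1.06. PPP1R15A, which reverses the stress block on translation, rose from 15.6 ± 1.28 to 231 ± 10.2 FPKM, ATF3 from 4.04 ± 0.121 to 54.5 ± 0.487 and ASNS, asparagine synthetase, from 8.52 ± 0.616 to 42.4 ± 0.78. Of 4 heat shock genes 4 rose, with HSPA1A from 25.4 ± 0.736 to 91.2 ± 5.03 FPKM. HSPA8 of that list rose from 221 ± 10.4 to 445 ± 21.4 FPKM but had a log2 fold change of -0.09 with quantile normalization. Of 7 p53 targets, 6 rose and 1 fell (median 1.49), with GDF15 from 7.23 ± 0.251 to 66.7 ± 4.38 FPKM and SESN2 from 3.61 ± 0.312 to 11.9 ± 0.315. Of 9 mesenchymal genes, 8 rose and 1 fell, with SERPINE1 from 115 ± 3.6 to 609 ± 28.6 FPKM. VIM of that list rose from 133 ± 3.82 to 318 ± 9.2 FPKM but had a log2 fold change of -0.06 with quantile normalization. Of 6 hypoxia and glycolysis genes, 5 rose and 1 fell, with the peptide hormone ADM from 21.8 ± 0.535 to 214 ± 7.21 FPKM.

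Every listed mitochondrially encoded gene was lower in resistant cells. Of 12 mitochondrially encoded genes 0 rose and 12 fell (median -1.57), with MT-CO3 from 7789 ± 362 to 2082 ± 38.3 FPKM. Of 35 G2/M genes the table listed 9, and of the 8 tested 1 rose and 7 fell (median -0.83), with the proliferation marker MKI67 from 10.5 ± 1.18 to 1.56 ± 0.0796 FPKM and KIF11 from 3.7 ± 0.135 to 1.56 ± 0.108, while MAD2L1 rose from 7.03 ± 0.726 to 16 ± 0.703. Of 39 ribosome biogenesis genes 3 were listed, and all 3 fell, with the RNA polymerase I subunit POLR1A from 5.56 ± 0.0913 to 1.25 ± 0.111 FPKM. Of 42 ribosomal protein genes 5 were listed, and all 5 rose (median 1.09). Their median was -0.18 with quantile normalization, under which RPS24, up from 103 ± 8.35 to 220 ± 10.9 FPKM, had a log2 fold change of -0.22. Of 7 basal genes 6 rose and 1 fell, of 5 Wnt targets 4 rose and 1 fell, and of 7 interferon-stimulated genes 4 rose and 3 fell. Of 6 HOX genes 3 rose and 3 fell, of 4 luminal genes 1 rose and 3 fell, and of 3 NRF2 genes 2 rose and 1 fell. The 3 cholesterol synthesis, 2 homologous recombination, 2 fibroblast and 1 S phase genes fell, the 1 ovarian gene rose, and 1 immune gene rose and 1 fell. Of the study genes, C12orf43 rose and TP53 fell. These counts were the same adjusted over the list alone.

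**Figure D4:**
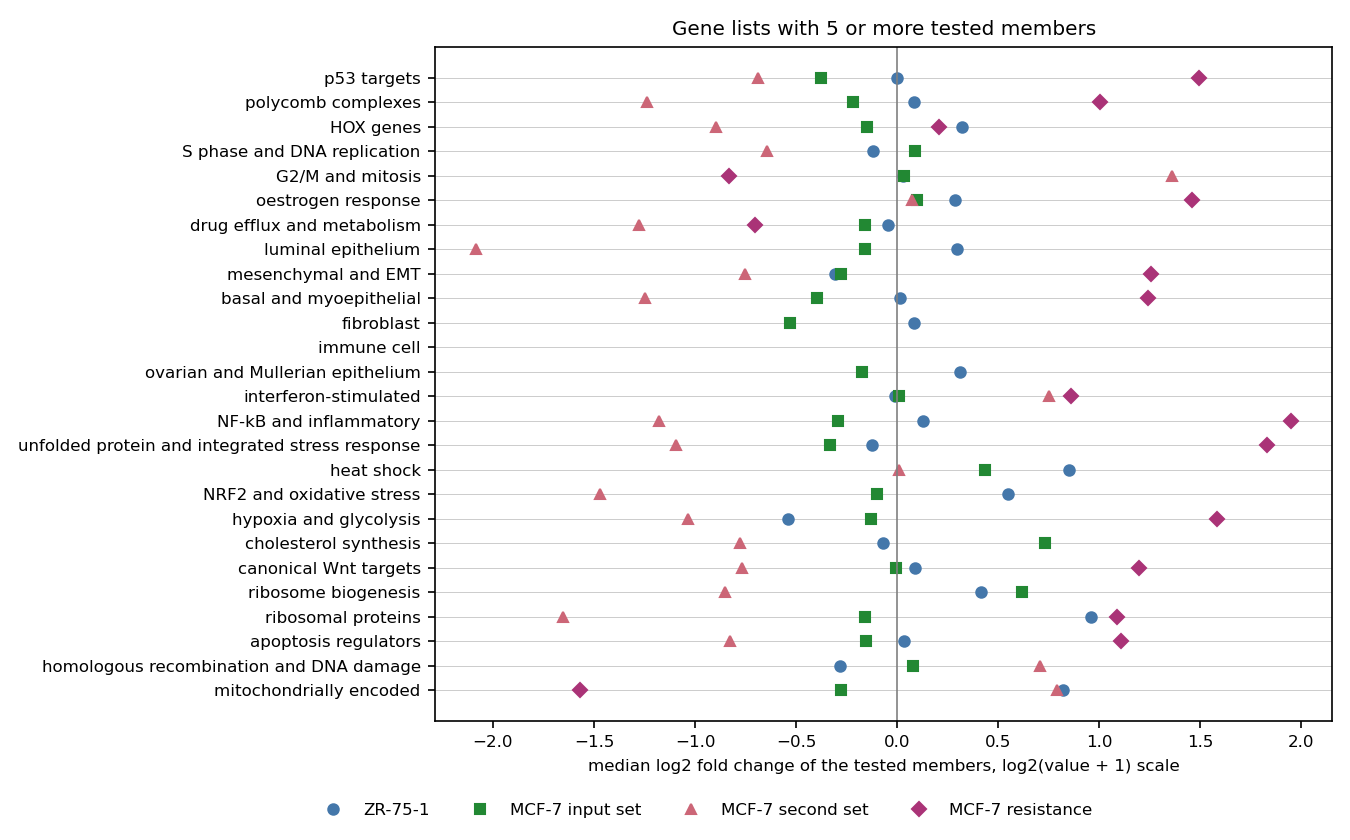
Median log2 fold change of the tested members of each gene list with 5 or more, on the log2(value + 1) scale; symbols stand for the 4 comparisons and the vertical line marks 0. Ribosomal proteins stood at 0.96 in ZR-75-1 and -1.65 in the second set, where quantile normalization gave 0.40, and mitochondrially encoded genes at -1.57 in resistant cells.

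Genes changed in both of 2 overexpression experiments were then counted. The ZR-75-1 experiment and the second set moved most shared genes in opposite directions. Of 4080 genes changed in both, 13.0% moved the same way, and fold changes had a Pearson r of -0.63 and a Spearman rho of -0.64 over 7016 genes tested in both, which are not independent replicates. Up calls shared were 273 against 1092 expected from independent lists, and down calls 257 against 869 (1-sided Fisher's exact test for fewer than expected across genes, adjusted p = 2.26e-292 for down calls and too small to be computed for up calls). ZR-75-1 and the input set shared 4 up calls against 1.33 expected (adjusted p = 0.0723) and 1 down call against 0.923, with r = 0.087. With a log2 fold change of 1 or more required, 3 up calls were shared against 0.238 expected (adjusted p = 0.00481). These counts include C12orf43, which is on the plasmid of both. Without it, 3 up calls were shared against 0.994 (adjusted p = 0.218), and with the fold change required 2 against 0.178 (0.0609). The input set and the second set shared 1 up call, C12orf43 itself, and 2 down calls against 0.842 and 1.16, with r = -0.033.

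Against resistance, the ZR-75-1 experiment shared 317 up calls against 228 expected and 335 down calls against 239 (1-sided Fisher's exact test across genes, Benjamini-Hochberg over 6 tests, adjusted p = 3.89e-21 and 3.62e-27). Of 940 genes changed in both, 69.4% moved the same way. The correlation was r = 0.24 over 1675 genes, and 0.039 with the length trend removed. With a log2 fold change of 1 or more, 69 up calls were shared against 32.8 (adjusted p = 3.24e-13) and 14 down calls against 8.61 (adjusted p = 0.0956). The second set shared 168 up calls with resistance against 211 expected and 287 down calls against 330 (with the length trend removed 222 against 226 and, as an excess, 214 against 194, adjusted p = 0.0127), with 42.2% of 1078 genes moving the same way and r = -0.17, or 0.030 with quantile normalization. The input set shared 1 up call, C12orf43, and 0 down calls with resistance, with r = -0.21. The resistance and second-set tables hold only selected genes, which limits what the expected numbers stand for.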

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

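Of the tests in this part, those of swapped labels and of length and scaling for the ribosomal proteins of ZR-75-1 were chosen after the result was seen. In 7 gene lists, taking the median of the members in each library, all 3 overexpression libraries lay on one side of the 3 controls in an experiment and on the other side in another. The differences between experiments were not tested. Mean log2 differences for ribosomal proteins were 0.95 in ZR-75-1, -0.28 in the MCF-7 input set and -2.02 in the MCF-7 second set. For ribosome biogenesis they were 0.51, 0.68 and -1.08. Between ZR-75-1 and the second set, p53 targets stood at 0.080 and -1.09, oestrogen response genes at 0.40 and -0.79, and NRF2 and oxidative stress genes at 0.49 and -1.76. The sides in the second set depend on scaling, since medians of its members' fold changes with median-of-ratios scaling and quantile normalization were 0.28 and 0.39 for p53 targets, 0.80 and 0.44 for oestrogen response, -0.44 and 0.57 for NRF2 and oxidative stress, and 0.12 and 0.13 for ribosome biogenesis. Without them that median was 0.07 for oestrogen response, and for p53 targets in ZR-75-1 it was -0.0029. In ZR-75-1 and the input set it was -0.072 and 0.73 for cholesterol synthesis, and 0.084 and -0.53 for fibroblast genes, of which 0 of 5 changed in the input set. Between ZR-75-1 and the input set, cholesterol synthesis genes stood at -0.38 and 0.58, and fibroblast genes at 0.59 and -1.50.

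Behind several of these lists, fold changes of ZR-75-1 and the second set ran opposite across genes, with ribosomal proteins up in ZR-75-1 and, except under quantile normalization, down in the second set. Trends in GC content or length, as fitted, are argued against as the whole cause by an r of -0.464 with the GC trend removed. It was -0.508 with the length trend removed and -0.371 with both removed. The second set holds only genes selected for a difference, so a fitted trend may leave a part of such a bias. Its fold changes still followed the genomic span of genes, with a rho of 0.31 with the GC trend removed and 0.18 with both removed. A part played by such trends thus stays open. Swapped group labels are argued against by C12orf43, which was at least 16.1 times higher in the overexpression libraries of both experiments. The ribosomal protein median in ZR-75-1 stayed at 0.742 with the length trend removed, 0.832 with the GC trend removed, 0.959 with median-of-ratios scaling and 0.519 with quantile normalization, and in the second set at -0.854 and -1.16 with those trends removed. Scaling stays open for the second-set ribosomal proteins, at -0.624 (SE 0.227) with median-of-ratios scaling, which is within its spread of the bound of -0.5 set beforehand, and 0.398 with quantile normalization. Another cell line in the second set's overexpression libraries, whose header carries ZR-75-1, may contribute and cannot be told apart, since fold changes followed the ZR-75-1 minus input set controls with a rho of 0.505, but 0.141 with GC content held, across tables normalised separately, and a difference between the lines in their response was not tested.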

How the results depend on the processing

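Removal of length and GC trends, voom on recovered reads, and lists or overlaps refitted without single libraries or under quantile normalization were chosen after seeing the data, as were overlaps without C12orf43. C12orf43 kept its direction and its call in all 4 comparisons under every alternative run. With a log2 fold change of 1 or more, changed genes numbered 997 in ZR-75-1, 5135 in the second set and 1141 in resistance, by the threshold's own construction. In resistance they numbered 1072 with a filter at 5, since fewer genes were tested. Against 8 in the input set, 4 genes changed with a pseudocount of 0.1, 4 with 0.01, 4 with no filter, 5 with a filter at 5, 3 with the replicate block, 21 with voom and 2 to 3 without 1 library; the cause was not tested. In ZR-75-1, leaving out 1 library gave 5037 to 9436, the highest without control 3. Lists past camera fell to 0 in ZR-75-1 and 0 in the input set with an estimated correlation, and leaving out 1 library gave 9 to 11 and 5 to 7. In the test for excess, overlaps past the threshold numbered 1 between overexpression experiments and 1 with resistance when a log2 fold change of 1 or more was required, and 0 and 1 with C12orf43 also left out. In the test for fewer than expected at that threshold, ZR-75-1 and the second set still passed in up and down calls (adjusted p = 2.7e-28 and 8.78e-06), and the second set and resistance in up calls (0.000877).

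Directions turned in these cases, and the cause was not tested. With quantile normalization, TP53 in ZR-75-1 was at -0.012, PLK1 and MT-ND3 in the second set at 0.57 and 0.40, and VIM, HSPA8 and RPS24 in resistance at -0.057, -0.093 and -0.22. With the GC trend removed, TP53 in ZR-75-1 was at -0.016 and PLK1 in the second set at 0.13. With the length trend removed, MDM2 in ZR-75-1 was at 0.0043 and MT-ND3 in the second set at 0.042. With both removed, MDM2 was at 0.069 and PLK1 at 0.0095. CDKN1A in the input set lay between -0.40 and 0.42 without 1 library, below 0 without control 1 (-0.30), control 2 (-0.076) or overexpression 1 (-0.40). The other values of named genes kept direction and call in 847 cases in ZR-75-1, 199 in the input set, 688 in the second set and 743 in resistance. In further cases a call was lost, 16 in ZR-75-1, 62 in the input set, 3 in the second set and 0 in resistance, or gained, 7 in ZR-75-1 and 2 in the input set.

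The replicate block gave 6469 changed genes in ZR-75-1, 3 in the input set, 8686 in the second set and 2095 in resistance, and ended the camera calls of cholesterol synthesis in ZR-75-1 (adjusted p = 0.0591) and of ribosomal proteins in the input set (0.0769). Deviations of libraries with the same number correlated at -0.09, 0.10 and 0.00 in ZR-75-1 and -0.02, 0.02 and -0.01 in the input set. Values were -0.04, 0.29 and 0.16 in the second set and -0.01, -0.07 and 0.24 in resistance. Libraries of the second set with different numbers correlated at -0.29 to 0.16. With 3 libraries per group, such values can neither show nor exclude that the numbers pair the libraries. The authors' threshold was to be used only where a table gave a comparison without libraries, which none did, so that alternative was not run.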

Other observations

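The tests of depth and of an overexpression effect for ESR1, and the splits of the libraries for genes changed, were chosen after the result was seen. Polycomb genes, which encode chromatin repressors such as BMI1, moved both ways. In ZR-75-1, 8 rose and 7 fell of 28 (10 and 9 adjusted over the list alone, camera adjusted p = 0.963), with CBX6 up from 7.83 ± 0.289 to 11.4 ± 0.289 FPKM (log2 fold change 0.16 and not passing with the GC trend removed) and PHC3 down from 9.83 ± 2.06 to 5.27 ± 0.207. In the input set 0 of 24 changed (1 fell adjusted over the list alone, 0.364). In the second set 9 rose and 12 fell of 21, with a median log2 fold change of -1.24 that was 0.26 with quantile normalization, and RING1 went down from 61.1 ± 3.39 to 9.98 ± 0.797. In resistant cells 4 rose and 2 fell of 6, with CBX2 down from 22.3 ± 1.2 to 6.74 ± 0.259 FPKM. Apoptosis regulators rose in 8 and fell in 7 of 24 in ZR-75-1 (8 and 9 adjusted over the list alone, 0.963), with BMF down from 6.19 ± 0.341 to 2.43 ± 0.287 FPKM and BCL2L1, which protects from apoptosis, up from 28.7 ± 3.52 to 50.7 ± 1.29. They changed in 0 of 22 in the input set by either adjustment (0.663). In the second set 7 rose and 9 fell of 16 (median -0.83, and 0.16 with median-of-ratios scaling). In resistant cells 4 rose and 2 fell of 6, with PMAIP1, which promotes apoptosis, up from 5.05 ± 0.412 to 34.5 ± 2.33 FPKM, the protective MCL1 up from 25 ± 1.33 to 106 ± 10.6 and CASP9 down from 20 ± 0.942 to 4.67 ± 0.52.

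Oestrogen response genes in ZR-75-1 rose in 8 and fell in 4 of 18 (10 and 4 adjusted over the list alone, camera adjusted p = 0.475), with cyclin CCND1 up from 23.6 ± 1.44 to 41.4 ± 2.08 FPKM. In the input set 0 of 17 changed (1 fell adjusted over the list alone, 0.813), and STC2 was at 33.4 ± 2.7 against 8.71 ± 1.92 FPKM. In the second set 5 rose and 5 fell of 10 (median 0.07, mean -0.23), and in resistant cells 4 rose and 2 fell of 6, with STC2 up from 13.7 ± 0.636 to 124 ± 5.97 FPKM and the growth factor AREG from 1.58 ± 0.361 to 12 ± 0.678. Drug efflux and metabolism genes rose in 8 and fell in 7 of 23 in ZR-75-1 by either adjustment (0.963), with the efflux pump ABCG2 up from 5.88 ± 0.607 to 10.1 ± 0.377 FPKM. In the input set 0 of 23 changed (1 fell adjusted over the list alone, 0.153). In the second set 4 rose and 13 fell of 17 (median -1.28, and -0.56 and -0.53 with median-of-ratios scaling and quantile normalization), with GSTP1, which conjugates drugs to glutathione, down from 2127 ± 226 to 184 ± 7.98. In resistant cells 2 rose and 5 fell of 7, with CYP1A1 up from 1.93 ± 0.0853 to 21 ± 0.936 FPKM and ABCA3 down from 16.4 ± 0.577 to 7.19 ± 0.319.

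ESR1 lay near 0 in the ZR-75-1 libraries and was not listed in the MCF-7 input set, both labelled as lines known for the oestrogen receptor. Low depth is argued against, since ESR1 at 1 FPKM would have given at least 198 reads in each ZR-75-1 library, and so is an effect of C12orf43 overexpression, since the highest control was at 0.0767 FPKM. Libraries from another line than the label names may account for it, since MTAP, which MCF-7 is known to lack, was at 2.0 FPKM in the lowest of the 6 input set libraries. CDKN2A, known to be lost with it, was at 35.0 FPKM in the lowest library of the input set and at 137 in that of the second set, so the doubt reaches both. Sensitive cells of the resistance comparison, also labelled MCF-7, had VIM at 133 FPKM and CDH1 at 0.229, much as in the ZR-75-1 controls. MTAP and CDKN2A were not listed for them. In the ZR-75-1 controls GATA3, CDH1 and KRT19 at 0.264, 0.388 and 0.412 FPKM, beside VIM at 149, also go with another line. KRT8 and KRT18 were high there, at 262 and 240 FPKM. For the resistance libraries and for ZR-75-1 the question stays open, because no such deletion marker was tested. Loss of the receptor within the labelled lines was not tested either and stays open.

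Resistant libraries held C12orf43 and FAM136A at levels far above the sensitive ones. A construct in them, with the label wrong, could account for this and cannot be told apart, since 42.2% of genes changed in the second set and in resistance moved the same way but 69.4% of those changed in ZR-75-1 and in resistance did. The first value meets the bound of 50% or fewer set beforehand against a construct, but that bound was wrong, because ZR-75-1 and the second set both carry the C12orf43 plasmid by their labels and yet moved the same way in 13.0% of genes. The share between the second set and resistance was 29.5% with the GC trend removed, 37.8% with GC and length trends removed and 51.7% with the length trend removed. Of the listed neighbours within 1 Mb of either gene, 5 of 9 were higher in resistant cells, in a table of selected genes. Near C12orf43, 88 genes are annotated and 6 were listed. Of these, 2 were higher and 4 lower, which argues against a gain of the whole stretch there. Near FAM136A, 62 are annotated and 3 were listed, all higher. Annotated genes that were not listed did not meet the selection or may not be expressed. Copy gain of a shorter segment at C12orf43, or of the segment around FAM136A, stays open. Induction of both genes with resistance was not tested.

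Each comparison has 10 splits of its 6 libraries, too few for a share under 0.05, and the labelled split gave the largest count in each, which is 1 of 10. It gave 7283 changed genes in ZR-75-1 against at most 0 in another split, 8 against 2 in the input set, 8678 against 0 in the second set and 2094 against 0 in resistance. The second set and the resistance table hold only genes selected for a difference between the labelled groups. Their split counts follow from that selection, so nothing is concluded from them. Lists past camera numbered 10 against 8 in ZR-75-1 and 8 against 3 in the input set.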
